A study of Populus x canadensis with 3 samples.

How the data were processed

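Small RNA libraries were made from total RNA of poplar roots with standard Illumina protocols, per the labels' protocols, after RNA of the same treatment had been mixed in equal parts. There were 3 libraries, 1 for each pHBA dose of 0, 2 and 4 mML-1 as labelled, so samples were grouped by their dose label and no group has replicates. The unit is not explained in the labels, and millimolar is presumed. Base calls were converted with bcl2fastq 1.8.4, per the submitters' processing notes. The aligner, the counting tool, the miRNA database release and the genome build are not given in the sources used here, and genome positions were not analysed here.

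The authors deposited 1 table with 673 entries, which hold 472 distinct sequences of 18 to 25 nt. An entry pairs a miRNA name with a sequence. The names point to Populus trichocarpa (ptc) for 258 sequences and to other species for 190, and 24 are predicted (PC). A capital MIR with p5 or p3 marks a hairpin strand that is not registered as a mature miRNA, and suffixes such as R+1 or 1ss1TC mark ends or substitutions that differ from the registered sequence. For each library the deposited table gives an expected count, which need not be whole. Reads appear to have been divided between entries, by a rule that is not given in the sources used here. Of the values of all entries, zeros included, 60.2% were within 0.0001 of a whole number in PHBA 0, 65.5% in PHBA 2 and 64.3% in PHBA 4. The same value stands at each entry of a sequence (151 sequences have more than 1 entry, at most 12), so each sequence was counted once. Some different sequences also share exactly the same 3 values, 11 of those tested, and members of 1 family that differ by a base cannot be told apart with certainty by such counts.

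The deposited table also gives a normalized signal per sequence, which is the expected count times 1 constant per library, 0.498 in PHBA 0, 1.29 in PHBA 2 and 1.50 in PHBA 4. It has no length term, and how the authors chose the constants is not given in the sources used here. These normalized reads were used as deposited. Their totals were 715066, 701992 and 571200, which are not equal, so equal totals and median-of-ratios factors were tried as alternatives. The median log2 fold change of the tested sequences as deposited was -0.03, 0.01 and 0.03 for PHBA 2 against PHBA 0, PHBA 4 against PHBA 0 and PHBA 4 against PHBA 2.

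Totals over distinct sequences of the table were 1434442, 542913 and 380800 reads, so values of PHBA 4 rest on the fewest reads. They are reads on the listed miRNAs, and total library depth was not analysed here. The table lists few values above 0 and below 2.5 reads (1, 3 and 1 sequences), and 51, 107 and 123 sequences are listed at 0. A 0 may therefore stand for a value under a minimum, and no fold is given against it.

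The design had been fixed for an unspecified unit before the data were examined. A sequence was tested when its mean over the 3 libraries was at least 10 normalized reads (289 sequences). It was called at least 2-fold higher or lower when log2 of (a + 1) over (b + 1), with a pseudocount of 1, was at least 1 in size. This scale understates differences of low values. Through the pseudocount the 2-fold counts include sequences listed at 0 in 1 of the libraries compared, 9 of 75 for PHBA 2 against PHBA 0, 13 of 130 for PHBA 4 against PHBA 0 and 16 of 97 for PHBA 4 against PHBA 2. Folds in the text are ratios of normalized reads without the pseudocount. Their 95% intervals are exact conditional binomial (Clopper-Pearson) intervals from expected counts rounded to whole reads, and shares have Wilson 95% intervals. Reads without molecular identifiers are not independent molecules, so both cover counting error only.

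Families merge all letters and strands of 1 miRNA number. The 10 lists were fixed before the data were examined. They are auxin signalling (miR160, miR167, miR390, miR393), copper-responsive (miR397, miR398, miR408, miR857, miR1444), phosphate and sulfate (miR395, miR399, miR827), phase change (miR156, miR157, miR172, miR529, miR535), MYB and TCP (miR159, miR319, miR828, miR858), meristem and organ development (miR164, miR165, miR166, miR169, miR171, miR396), small RNA machinery (miR162, miR168, miR403), NBS-LRR (miR472, miR482, miR1448, miR2118), pentatricopeptide repeat genes (miR475, miR476) and annotations doubted as tRNA or rRNA fragments (miR894, miR5139, miR5368, miR6300, miR6478). A list is described by its median log2 fold change, the percentile of that median among 10000 random lists of the same size matched on mean expression in 10 bins, and its summed value. Percentiles under 2.5 or over 97.5 are called outside the range of random lists. They describe these libraries and are not p-values. Random lists draw single sequences without regard to family, while the fixed lists hold several sequences and strands of the same family. Such sequences may move together, so a fixed list can fall outside this range more easily than a list of unrelated sequences.

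Single miRNAs named are those of a rule fixed in advance. It takes the 10 with the largest and the 10 with the smallest log2 fold change for each pHBA dose against PHBA 0 and the 5 of each between the doses, all with a mean of at least 10, identical sequences counted once and ties broken by the higher mean. It adds the 10 most abundant and up to 4 members of each list by mean. Not all of them are printed. Families and sequences named outside it were chosen after their values were seen, and these are ptc-miR403a in the report and, in the closing section, the families without a list, the strand pairs and the 24 nt members of miR6300.

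The steps were run in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. They were tested on simulated data, 20 draws over 472 sequences of which 200 were changed. At a 4-fold change 98.4% were called in PHBA 2 against PHBA 0, 99.3% in PHBA 4 against PHBA 0 and 97.7% in PHBA 4 against PHBA 2. At exactly 2-fold, the threshold, 49.2%, 50.9% and 50.4% were called. Unchanged sequences were called in 0.775%, 1.32% and 2.25%, and the intervals held the true ratio in 96.9%, 96.0% and 95.9%. The simulated libraries held counting noise alone. These rates therefore say nothing of spread between separate libraries or RNA pools.

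The alternatives were pseudocounts of 0.1 and 10, no minimum or a mean of at least 100, the other scalings, every entry of the table, thresholds of 1.5-fold and 3-fold, sums in place of medians, and shares without the most abundant miRNA. Added after seeing the data were counts without the fragment list and sequences under 20 nt, counts with PHBA 0 and PHBA 2 thinned to the PHBA 4 read total, and sums of the fragment list without gma-miR6300. Overlap between the comparisons that share PHBA 0 was set beside 100 simulated draws of unchanged libraries.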

Results

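Small RNA was sequenced from roots of the hybrid poplar Populus × euramericana "Neva" after exposure to para-hydroxybenzoic acid (pHBA), a phenolic acid that plants release into soil and that can inhibit root growth. Rooted cuttings had been in water culture for 60 days and then received pHBA for 3 days at a labelled dose of 0, 2 or 4 mML-1, presumably millimolar. The libraries are called PHBA 0, PHBA 2 and PHBA 4 here. The question put to them is which microRNAs (miRNAs) differ in roots that received the acid. RNA of the same treatment was pooled in equal parts before sequencing, so each dose is 1 library and the set is 3 libraries. No difference has a replicate check, no p-value is given, and each interval in brackets covers counting error only. The table lists 472 distinct sequences of 18 to 25 nt. Reads on them, each sequence counted once, came to 1434442 in PHBA 0, 542913 in PHBA 2 and 380800 in PHBA 4.

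The root libraries were dominated by the miRNA families that act on NBS-LRR resistance genes, the intracellular immune receptors of plants. The miR472, miR482 and miR1448 families together held 70.1% of normalized reads in PHBA 0, 70.7% in PHBA 2 and 61.9% in PHBA 4, each sequence counted once. Over all entries reads came to 2358668, 823554 and 594654. If reads were divided between entries, counting once lowers the share of sequences with several entries. Shares over all entries were not computed. The most abundant sequence was ptc-miR472b in PHBA 0 (20.4%) and PHBA 2 (20.7%), and ptc-miR472a in PHBA 4 (19.1%). Sequences of 22 nt made up 71.3% of reads in PHBA 0 (Wilson 95% interval 71.2 to 71.3), 71.2% in PHBA 2 (71.1 to 71.4) and 62.1% in PHBA 4 (61.9 to 62.3). Those of 21 nt made up 25.5%, 24.2% and 29.2%. Sequences of 18 and 19 nt took 0.329% of reads in PHBA 0, 0.670% in PHBA 2 and 3.60% in PHBA 4 (3.54 to 3.66). A fixed list of annotations that are doubted as fragments of tRNA or rRNA took 0.676%, 2.08% and 3.97%. Its 29 sequences came from miR6300 (23), miR5368 (5) and miR6478 (1), while its other families, miR894 and miR5139, were not seen among the listed sequences. Of its 25 tested sequences 20 were of miR6300. That list is taken as a marker of fragment reads, although its sequences were not matched to tRNA or rRNA here. Its share was higher at both doses than in PHBA 0. Most of the further step to PHBA 4 rests on gma-miR6300, and without it, an alternative chosen after seeing the data, the shares were 0.567%, 1.83% and 1.97%. The number of sequences above 0 was 421, 365 and 349.

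PHBA 2 was first set against PHBA 0. At the lower dose, miRNAs of the copper-responsive list were higher and those of the meristem and organ development list were lower at the median. The summed copper-responsive value was 1.93-fold higher (1.87 to 1.99), led by the polyphenol oxidase regulator miR1444, at 2403 normalized reads in PHBA 0 and 6009 in PHBA 2. The miR396 family, which represses growth-regulating factors, was 1.78-fold lower (1.75 to 1.82). The miR403 family was 2.20-fold lower (2.05 to 2.38) in sum, mostly from ptc-miR403c-5p at 2.52-fold lower (2.31 to 2.75), while ptc-miR403a, looked at after its values were seen, was 1.36-fold lower (1.16 to 1.60). The miR156 family, which represses SPL transcription factors, was 1.43-fold higher (1.41 to 1.46) in sum, a rise carried by ptc-miR156g. Of 289 sequences with a mean of at least 10 normalized reads, 75 differed at least 2-fold, 47 higher and 28 lower, and the counting interval excluded a ratio of 1 for 65 of them. Without a minimum on the mean the split turned, with 81 higher and 110 lower.

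In the copper-responsive list, 4 of 10 members were at least 2-fold higher at the lower dose and 0 were lower. The median log2 fold change was 0.84, at the 99.4 percentile of random lists of the same size and expression. Its most abundant member, ptc-miR1444a_R+1 (TCCACATTCGGTCAATGTTCC), was 2.71-fold higher (2.59 to 2.84). The superoxide dismutase regulator ptc-miR398b (TGTGTTCTCAGGTCGCCCCTG) stood at 62.6 and 183 normalized reads, 2.92-fold higher (2.27 to 3.72). ptc-miR408-3p was 1.30-fold higher (1.22 to 1.38). The laccase regulator miR397 went the other way, 1.75-fold lower (1.45 to 2.12). The doubted fragment list moved with this group, with a median of 1.33. Among members with a mean of at least 100 the percentile of the copper-responsive list was 93.8, inside the range of random lists.

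In the meristem and organ development list, 8 of 66 members were at least 2-fold lower in PHBA 2 and 1 was higher. The median was -0.29, at the 0.475 percentile. ptc-miR396a (TTCCACAGCTTTCTTGAACTG) stood at 20612 and 10190, 2.02-fold lower (1.97 to 2.07), and ptc-miR171l-5p_1ss1TC was 3.01-fold lower (2.68 to 3.39). miR164, which represses NAC transcription factors, was 1.65-fold lower (1.57 to 1.74), miR171 was 1.51-fold lower and miR166, the HD-ZIP III regulator, was 1.24-fold lower. miR169, with 26 tested sequences the largest family of the list, stood at 18687 and 18425. The percentile of the list was 6.20 among members with a mean of at least 100 and 2.57 without a minimum, both inside the range of random lists. The doubted fragment list, at 3.02 times its PHBA 0 sum, moved in the opposite direction.

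Apart from the copper-responsive, meristem and fragment lists, the lists lay inside the range of random lists at the lower dose. The median was -0.28 for auxin signalling (percentile 10.4; 0 higher and 3 lower of 24) and -0.10 for phase change (40.3; 0 higher and 2 lower of 19), where the summed value was instead 1.41-fold higher. It was -0.47 for MYB and TCP (3.27; 0 higher and 1 lower of 10), with percentiles of 1.86 at a mean of at least 100 and 1.15 with every entry counted, and -0.40 for small RNA machinery (7.26; 0 higher and 1 lower of 8). For NBS-LRR it was 0.04 (68.2; 0 higher and 1 lower of 16) and for the poplar miRNAs acting on pentatricopeptide repeat genes -0.08 (46.4; 0 of 8 in either direction). The phosphate and sulfate list had 1 member to test, ptc-miR827, at 11 and 7.76 normalized reads, with a median of -0.45 (32.9). Within lists, ptc-miR156g (TTGACAGAAGATAGAGAGCAC) was 1.65-fold higher (1.62 to 1.68), ptc-miR162a was 1.43-fold higher (1.36 to 1.51) and ptc-miR159a was 1.36-fold lower (1.31 to 1.41). The largest difference down to a value above 0 was in ptc-MIR393a-p3, 12.4-fold lower (4.13 to 130). This sequence, the less abundant strand of its hairpin, had a mean of 15.7 normalized reads, so its fold rests on few reads. Next was mtr-miR156b-3p_L-1_2ss4TC8TC, 5.44-fold lower (3.75 to 8.16), at 211 and 38.8 normalized reads.

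The fragment list had 20 of 25 members at least 2-fold higher at the lower dose and 1 lower (100 percentile). ptc-miR6478_R+2_1ss21GA was 4.54-fold higher (4.20 to 4.91) and gma-miR6300_R+4 was 4.18-fold higher (3.72 to 4.70). In this list 9 tested sequences share all 3 values with another, and with shared values counted once 15 of 20 were higher. Without this list and without sequences under 20 nt, an alternative chosen after seeing the data, 41 sequences differed at least 2-fold, 18 higher and 23 lower.

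**Figure D1:**
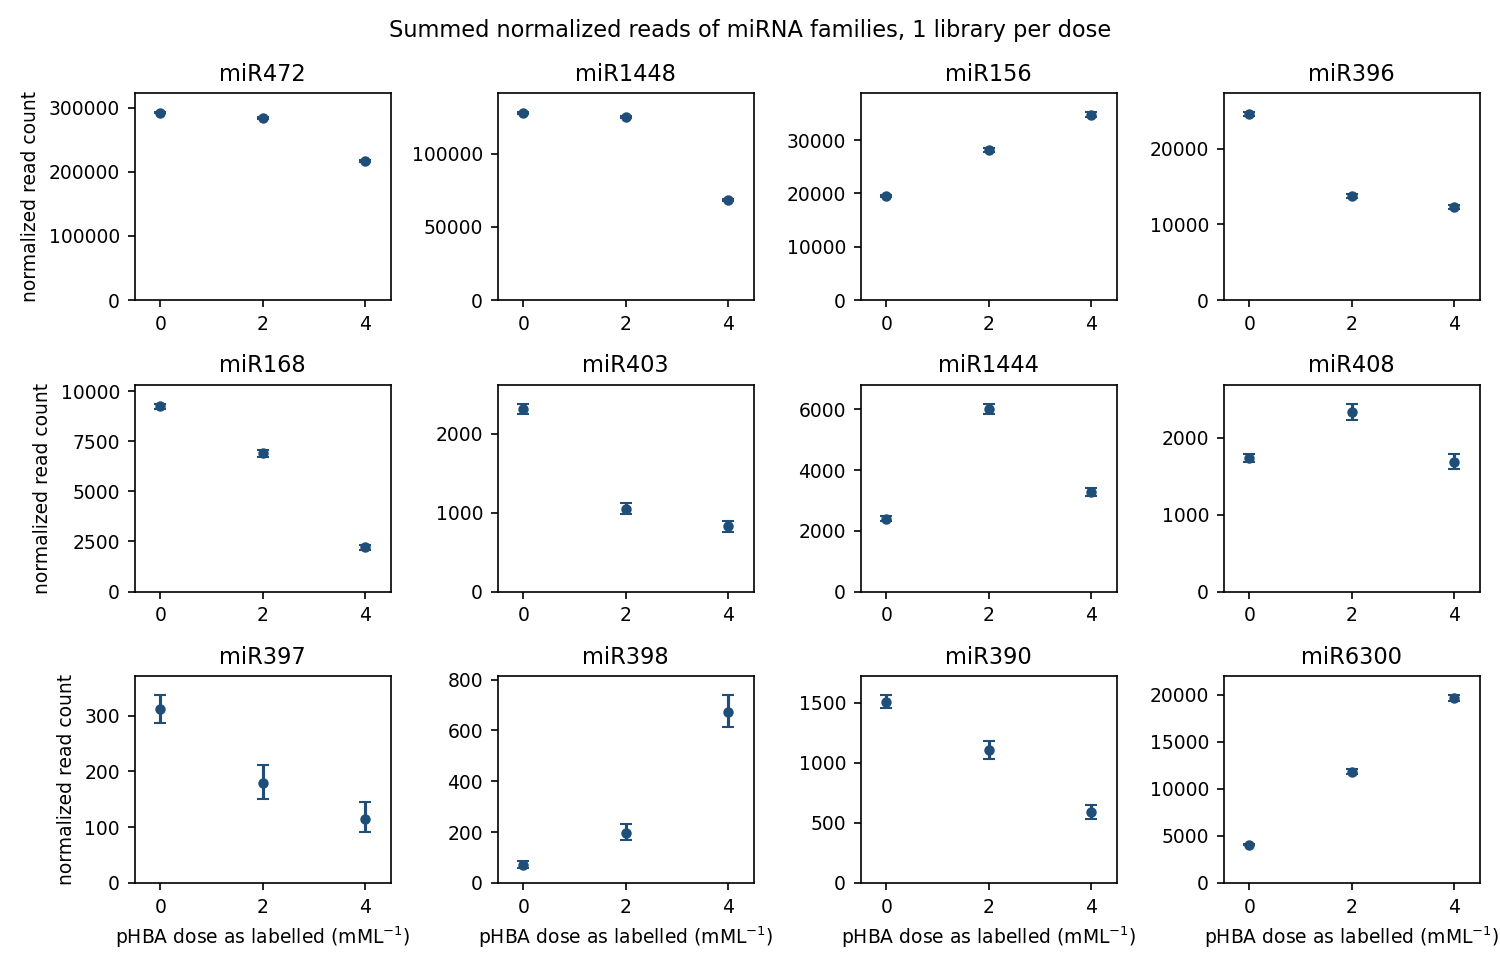
Summed normalized read counts of 12 miRNA families (vertical axes, each starting at 0) against the labelled pHBA dose in mML-1 (horizontal axes). Each point is 1 library and bars are exact Poisson 95% intervals, which cover counting error only. miR168 stood at 9234, 6885 and 2197, miR398 at 71.5, 197 and 674, and miR1444 was highest in PHBA 2 at 6009.

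PHBA 4 was then set against PHBA 0. At the higher dose 5 of 8 sequences of miR162, miR168 and miR403, the small RNA machinery list, were at least 2-fold lower. The miR398 family was higher, as was the miR156 family in sum, through ptc-miR156g. The miR168 family, which targets AGO1, the main Argonaute protein of the miRNA pathway, stood at 9234 and 2197, 4.20-fold lower (3.98 to 4.43). The summed miR403 family was 2.80-fold lower (2.57 to 3.07), with its 2 tested sequences at 3.37-fold and 1.47-fold lower, and miR390, which triggers trans-acting siRNAs against auxin response factors, was 2.55-fold lower (2.30 to 2.84). miR398 was 9.42-fold higher (7.76 to 11.4) and miR156 was 1.77-fold higher (1.75 to 1.8). Of 289 sequences, 130 differed at least 2-fold, 69 higher and 61 lower, and all 130 had counting intervals that excluded 1. With each library rescaled to the same total, log2 values of this comparison move up by 0.32 at the median, less where reads are few, and the split becomes 86 higher and 44 lower. Without a minimum on the mean it was 115 higher and 159 lower. Without the fragment list and sequences under 20 nt it was 29 higher and 61 lower of 90.

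In the small RNA machinery list, 5 of 8 members were at least 2-fold lower, 4 of them sequences of miR168 from both strands, and 0 were higher. The median was -1.55, at the 0.07 percentile, and the summed value was 2.30-fold lower (2.23 to 2.38). ptc-miR168a-5p (TCGCTTGGTGCAGGTCGGGAA) stood at 8133 and 1818, 4.47-fold lower (4.22 to 4.75), and the opposite strand of the hairpin, ptc-miR168a-3p, was 2.78-fold lower (2.43 to 3.20). ptc-miR403c-5p was 3.37-fold lower (3.04 to 3.76) and ptc-miR403a 1.47-fold lower (1.24 to 1.75). ptc-miR162a, which targets DCL1, was 1.40-fold higher (1.33 to 1.48). The doubted fragment list moved in the opposite direction, at 4.69 times its PHBA 0 sum, or 2.78 times without gma-miR6300.

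In the auxin signalling list, 8 of 24 members were at least 2-fold lower and 1 was higher, with a median of -0.65 at the 1.32 percentile. The members include both strands of some hairpins, paired here as in the closing section. For hairpins 160a, 167e, 167f and 393a, log2 fold changes of the more abundant strand were 0.68, -0.10, 0.07 and -0.35. Those of the less abundant strand were -0.71, -0.59, -1.15 and -3.11. For 390a it was the other way, with -1.55 for the more abundant strand and -0.36 for the other. ptc-miR390a (AAGCTCAGGAGGGATAGCGCC) was 2.93-fold lower (2.60 to 3.31), while ptc-miR160a was 1.60-fold higher (1.51 to 1.70) and ptc-miR167e stood at 1879 and 1757. The summed value was 1.12-fold lower (1.08 to 1.15), a direction that flips with equal totals, where its log2 fold change was 0.17. Among members with a mean of at least 100 the percentile was 12.8, inside the range of random lists. The fragment list median here was 1.85.

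The copper-responsive families parted at the higher dose. ptc-miR398b was 10.3-fold higher (8.38 to 12.6), the miR397 family was 2.70-fold lower (2.13 to 3.46) and miR1444 was 1.36-fold higher (1.29 to 1.43). miR408 stood at 1735 and 1684, a direction that flips with equal totals. In the list 2 of 10 members were at least 2-fold higher and 2 were lower, with a median of 0.01 (55.3 percentile), while the fragment list was higher.

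The NBS-LRR list was 1.42-fold lower in sum (1.41 to 1.42), with 1 of 16 members at least 2-fold higher and 5 lower, and a median of -0.43 at the 7.74 percentile. With equal totals the log2 of the sum was -0.18, against -0.50 as deposited. The list median and the miR472 family then each stood at -0.11. ptc-miR1448_L+1R+1 (TCTTTCCAACGCCTCCCATACC) was 2.14-fold lower (2.12 to 2.17), and ptc-miR472a and ptc-miR472b were 1.34-fold and 1.36-fold lower. ptc-miR482d-3p was 2.33-fold higher (2.28 to 2.39), while ptc-miR482b-5p (GGCATGAGGTGTTTGGCAAGA), at 118 and 7.50 normalized reads, was 15.8-fold lower (6.66 to 49.0). ptc-miR482b-5p is the less abundant strand of its hairpin, with a mean of 72.5 normalized reads against 976 for ptc-miR482b-3p. The latter had a log2 fold change of 0.44. The summed miR482 family was 1.19-fold lower as deposited and higher with equal totals. The fragment list moved in the opposite direction to this group.

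In the phase change list the members and the sum had different signs. Its median was -0.53 (5.86 percentile), with 7 of 19 members at least 2-fold lower and 1 higher, whereas the sum was 1.73-fold higher (1.70 to 1.75). ptc-miR156g carried the sum, at 13194 and 29959, 2.27-fold higher (2.23 to 2.31). ptc-MIR156a-p3 was 3.24-fold lower (2.78 to 3.79), and ptc-miR172h-5p was listed at 48.2 in PHBA 0 and at 0 in PHBA 4. In the meristem and organ development list 8 of 66 members were higher and 15 lower, with a median of 0.06 (counting interval -0.18 to 0.16; 57.6 percentile) and a sum 1.42-fold lower (1.40 to 1.43). With equal totals the log2 of that sum was -0.18, against -0.50 as deposited, and the median was 0.38. ptc-miR166a was 2.31-fold lower (2.25 to 2.37), ptc-miR396a 2.49-fold lower (2.42 to 2.56) and ptc-miR169n-3p 1.33-fold higher (1.28 to 1.37). The fragment list, at a median of 1.85, moved with the higher members of both lists, and 18 and 19 nt sequences held 3.60% of reads.

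For MYB and TCP the median was 0.17 (55.5; 0 higher and 2 lower of 10), with ptc-miR159a 1.41-fold higher (1.37 to 1.45). For pentatricopeptide repeat genes it was -0.16 (41.2; 0 higher and 1 lower of 8), with ptc-miR476a at 1186 and 1276. The phosphate and sulfate list gave 0.42 (49.3) from ptc-miR827, at 11 and 15. In the doubted fragment list 20 of 25 members were at least 2-fold higher and 0 lower (100 percentile), or 16 of 20 with shared values counted once. gma-miR6300, of 18 nt, stood at 785, 1762 and 11407 over the doses and was 14.5-fold higher (13.8 to 15.3) in PHBA 4 than in PHBA 0. The predicted 19 nt PC-5p-25263_273 stood at 2.99 in PHBA 0, was listed at 0 in PHBA 2 and stood at 636 in PHBA 4. Of the 29 tested sequences of 18 and 19 nt, 26 were at least 2-fold higher and 0 lower.

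**Figure D2:**
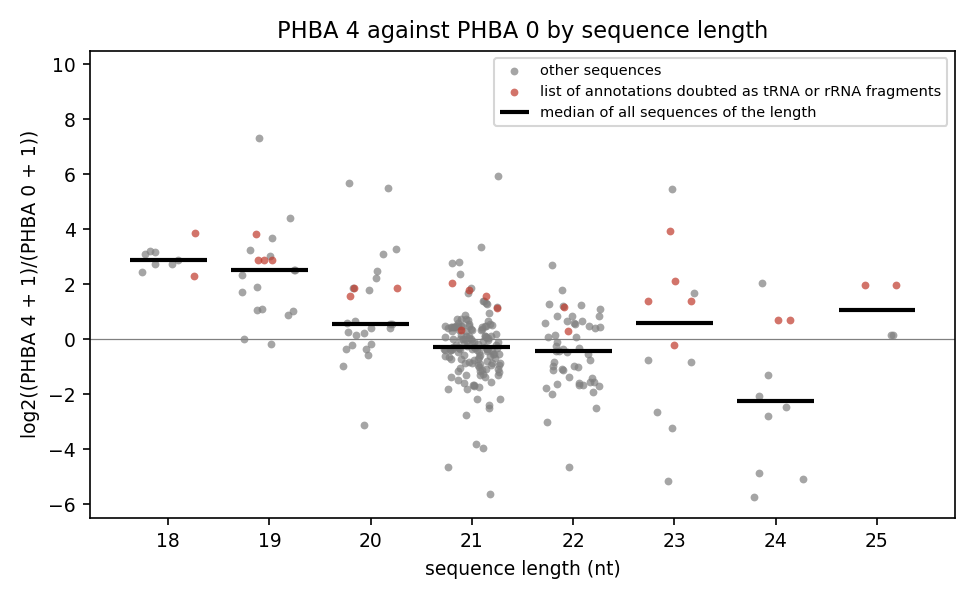
Log2 of (PHBA 4 + 1) over (PHBA 0 + 1) in normalized reads (vertical axis) against sequence length in nt (horizontal axis, points spread sideways at random). Each point is 1 of 289 sequences, red points belong to the list of doubted fragment annotations, and black bars are medians, which were 2.87 at 18 nt, -0.29 at 21 nt, 0.58 at 23 nt, -2.26 at 24 nt and 1.07 at 25 nt.

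PHBA 4 was also set against PHBA 2. Between these doses, 4 of 8 sequences of the small RNA machinery list and 5 of 16 of the NBS-LRR list were at least 2-fold lower at the higher dose. miR168 was 3.13-fold lower (2.96 to 3.32), miR1448 was 1.83-fold lower (1.81 to 1.85) and miR1444 was 1.84-fold lower (1.75 to 1.93). The other families of the small RNA machinery list differed less. miR403 was 1.27-fold lower (1.14 to 1.42), and miR162 stood at 2974 and 2913, a direction that flips with equal totals. miR398 was 3.41-fold higher (2.83 to 4.12) and ptc-miR159a was 1.92-fold higher (1.84 to 2.00). At least 2-fold differences were seen for 97 sequences, 50 higher and 47 lower, and 92 of them had counting intervals that excluded 1. Equal totals move log2 values up by 0.29 at the median, less where reads are few, and give 71 higher and 30 lower. Without the fragment list and sequences under 20 nt, 27 were higher and 43 lower of 70.

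The NBS-LRR list had a median of -0.65 at the 0.6 percentile, with 5 of 16 members at least 2-fold lower and 1 higher. ptc-miR1448_L+1R+1 was 2.05-fold lower (2.03 to 2.07) and ptc-miR482c-3p 1.70-fold lower (1.65 to 1.75). Its percentile was 4.47 among members with a mean of at least 100. The small RNA machinery list had a median of -0.76 at the 2.40 percentile, with 4 of 8 members lower and 0 higher, and the percentile was 8.06 without a minimum, 14.7 at a mean of at least 100 and 21.3 with every entry counted. ptc-miR168a-5p was 3.31-fold lower (3.11 to 3.53). Beside both groups the fragment list had a median of 0.32 (78.2 percentile), with 9 of 25 members higher and 2 lower, and its sum without gma-miR6300 was 1.14-fold lower (1.11 to 1.18).

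The remaining lists lay inside the range of random lists between the doses. Medians were -0.36 for auxin signalling (percentile 4.47; 2 higher and 4 lower of 24), where the sum was 1.07-fold higher, and -0.72 for copper-responsive miRNAs (2.87; 2 higher and 3 lower of 10). They were -0.34 for phase change (7.04; 0 higher and 5 lower of 19), where the sum was 1.22-fold higher, and 0.56 for MYB and TCP (91.6; 1 higher and 1 lower of 10). They were 0.20 for meristem and organ development (81.9; 12 higher and 5 lower of 66), where the sum was 1.08-fold lower as deposited and higher with equal totals, and -0.00 for pentatricopeptide repeat genes (48.9; 0 higher and 1 lower of 8). ptc-miR827 gave 0.87 for phosphate and sulfate (57.2). With every entry of the table counted the percentile was 0.3 for auxin signalling and 98.4 for MYB and TCP, and without a minimum it was 0.55 for copper-responsive miRNAs.

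Values were last read in order of dose. A set of 52 sequences was ordered upward over the 3 doses with at least a 2-fold difference between PHBA 0 and PHBA 4, and 49 were ordered downward. Among the upward ones were ptc-miR398b, ptc-miR156g and ptc-miR482d-3p, and among the downward ones ptc-miR168a-5p, ptc-miR166a, ptc-miR396a, ptc-miR390a and ptc-miR403c-5p. Of the 52, 15 belonged to the fragment list, and 0 of the 49 did. Without that list and without sequences under 20 nt, 23 were ordered upward and 49 downward. Irrespective of size, 149 of 289 sequences, or 51.6%, were ordered one way or the other, against 33.3% of the possible orders of 3 values. That share holds for 3 exchangeable libraries, which was not tested, so the excess shows no order with dose by itself. Equal totals turn the split into 62 upward and 36 downward. At least 2-fold higher at both doses than in PHBA 0 were 36 sequences, where independent lists would share 11.2 and draws with counting noise alone shared 0.25 on average. Lower at both were 12 sequences, against 5.91 and 0.04, and 4 went in opposite directions. At each dose 20 of the higher sequences belonged to the fragment list, and how many of the 36 did was not counted. Both comparisons use the same PHBA 0 library, so part of the excess may come from it. The draws hold no spread between separate libraries, so the excess over them does not measure a shared effect.

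**Figure D3:**
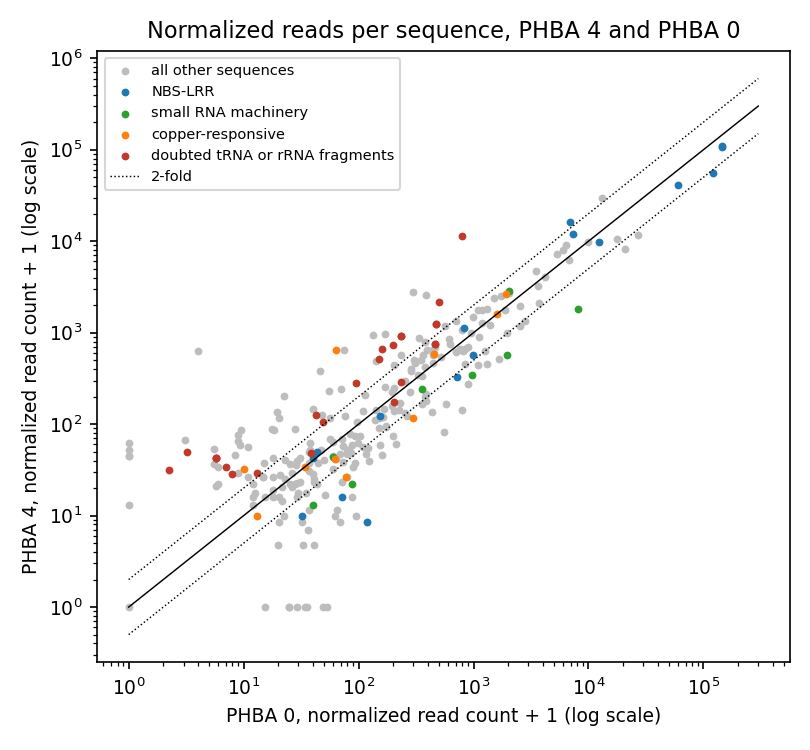
Normalized reads + 1 of each of 289 sequences in PHBA 0 (horizontal, log scale) and PHBA 4 (vertical, log scale), 1 library each, coloured by list. The solid line marks equal values and the dotted lines a 2-fold difference, and 69 sequences lay at or above the upper line and 61 at or below the lower one.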

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

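The counts without the fragment list and sequences under 20 nt, the thinned counts and the fragment sums without gma-miR6300 were chosen after seeing the data. No paired analysis was possible because each dose is 1 library. Of 44 alternative counts, 30 stayed within 1.5 times the value first given. Of 237 alternative list values 181 stayed within counting error, as did 724 of 888 values of single named miRNAs. Lists outside the range of random lists kept their sign under each single alternative. With sums and equal totals combined, however, the auxin list in PHBA 4 against PHBA 0 changed sign. Its summed log2 went from -0.16 as deposited to 0.17. Some other lists changed sign under a single alternative. As a sum, phase change in PHBA 4 against PHBA 0 went from -0.53 to 0.79. Meristem and organ development went from 0.06 to -0.50 in that comparison. Without gma-miR6300 the log2 of the summed fragment list was 1.66 in PHBA 2 against PHBA 0, 1.48 in PHBA 4 against PHBA 0 and -0.19 in PHBA 4 against PHBA 2, where with it the value was 0.63. Without a minimum the 2-fold counts were 191 (PHBA 2 against PHBA 0; 81 higher, 110 lower), 274 (PHBA 4 against PHBA 0; 115 higher, 159 lower) and 208 (PHBA 4 against PHBA 2), and at a mean of at least 100 they were 31, 53 and 26, since more or fewer sequences were tested. At 1.5-fold they were 135 for PHBA 2 against PHBA 0 and 168 for PHBA 4 against PHBA 2, and at 3-fold 31 and 56. With every entry counted PHBA 4 against PHBA 0 gave 203. Without the fragment list and sequences under 20 nt PHBA 2 against PHBA 0 gave 41. Sequences ordered with dose were 42 at a mean of at least 100 and 164 with every entry counted. Thinned to the PHBA 4 read total, counts were 77, 133 and 100, with 101 ordered. The fragment list median in PHBA 2 against PHBA 0 was 1.07 with a pseudocount of 10, 1.12 without a minimum and 1.65 at a mean of at least 100. In PHBA 4 against PHBA 0 it was 1.47 with a pseudocount of 10, 2.13 with equal totals and 2.23 as a sum. The auxin list in PHBA 4 against PHBA 0 was -1.17 without a minimum, -0.36 at a mean of at least 100, -0.27 with equal totals and -0.16 as a sum. Small RNA machinery in PHBA 4 against PHBA 2 was -0.42 both without a minimum and at a mean of at least 100, -0.47 with equal totals and -0.27 with every entry, and in PHBA 4 against PHBA 0 it was -1.01 with every entry. The meristem list in PHBA 2 against PHBA 0 was -0.12 at a mean of at least 100, and NBS-LRR in PHBA 4 against PHBA 2 was -0.36 with equal totals. Without the most abundant miRNA, 22 nt sequences made up 63.9%, 63.7% and 53.3% of reads. For the list values the cause was not tested. PHBA 4 rests on the fewest reads, and sequences listed at 0 were given no fold but stay in the 2-fold counts (9 of 75, 13 of 130 and 16 of 97). Of unchanged sequences simulated with counting noise alone 2.25% were called in PHBA 4 against PHBA 2, the shallowest pair.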

Other observations

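The families below and the strand comparison were chosen after their values were seen, as were the tests of scaling for short sequences, of the dose for short sequences and miR168, and of a shared shift of copper-responsive families. Several families outside the lists also differed. The poplar families miR6438, miR6427 and miR6445 were 2.37-fold (2.12 to 2.64), 1.70-fold (1.56 to 1.85) and 1.51-fold (1.41 to 1.61) higher in PHBA 4 than in PHBA 0. miR1450 was 1.66-fold lower (1.61 to 1.70) and miR6459 was 1.91-fold lower (1.60 to 2.29). miR530 peaked in PHBA 2, at 1455, 2136 and 1254 normalized reads. Of 10 tested 24 nt sequences, the length of heterochromatic small RNAs, 7 were at least 2-fold lower in PHBA 4 than in PHBA 0 and 1 was higher, with a median of -2.26. The summed 24 nt class was not lower, at 0.196% of reads in PHBA 0, 0.491% in PHBA 2 and 0.317% in PHBA 4. It includes gma-miR6300_R+6_1 and gma-miR6300_R+6_2 of the fragment list, each at 457, 1462 and 747 normalized reads. Among the lower ones ptc-MIR6446-p3 and ptc-MIR481d-p3_1ss9AG stood at 32.9 and 52.1 in PHBA 0 and were listed at 0 in PHBA 4. The fragment list, at 4.69 times its PHBA 0 sum, or 2.78 times without gma-miR6300, moved in the opposite direction.

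Strands of the same hairpin did not always move together. In PHBA 4 against PHBA 0, ptc-miR159a had a log2 fold change of 0.50 and the opposite strand ptc-MIR159a-p5_1ss21AT one of -1.67, and ptc-miR482b-3p had 0.44 against -3.81 for ptc-miR482b-5p. ptc-miR1448_L+1R+1 had -1.10 and the strand opposite it 0.72. Strands were paired by name and by a shared run of 6 bases with the reverse complement. The pairs are not all separate, since ptc-MIR6462c-p3 entered those of 6462b and 6462c alike. Over 45 pairs with both strands tested, the less abundant strand was the lower of the pair in 28 in PHBA 4 against PHBA 0. It was lower by more than 2-fold in 14 and higher by more than 2-fold in 8, with a median difference of -0.33. In PHBA 2 against PHBA 0 it was the lower in 24, lower by more than 2-fold in 2 and higher in 3, with a median difference of -0.10. In PHBA 4 against PHBA 2 it was the lower in 25, lower by more than 2-fold in 10 and higher in 7, with a median difference of -0.08.

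Short sequences stand apart in PHBA 4, where 26 of 29 sequences of 18 and 19 nt were at least 2-fold higher than in PHBA 0. Thinning PHBA 0 to the depth of PHBA 4 gave at most 2 such sequences in 100 draws, which argues against depth, and their median lay 3.04 above that of 21 nt sequences, although 1 factor per library moves both alike. General shortening of small RNAs may account for part of it, since 6 short sequences of the other 9 lists had a median of 1.05, with 4 of them at least 2-fold higher. Families outside the fragment list were also higher, with miR2916 9.32-fold higher (8.54 to 10.2; 2 of 2 tested sequences at least 2-fold higher), miR3630 7.73-fold higher (6.91 to 8.62; 3 of 3), miR8175 6.07-fold higher (5.62 to 6.56; 5 of 6, and 1 lower) and 6 of 6 miR6173 sequences higher. With 1 library per dose, RNA quality or library preparation and a response to the dose cannot be told apart.

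The miR168 family was lower in PHBA 4 under each scaling run, with log2 fold changes from -2.11 to -1.75. The other scalings shift this comparison by at most 0.32, so these factors do not account for it. Larger errors of scaling were not tried. Of 79 sequences of 21 nt with a mean of at least 100, 2.53% were as low as ptc-miR168a-5p. That share was bound to be small, since miR168 was picked for its low values. The median of the 79 was -0.11, far above the miR168 family, which argues against an equal loss of all such sequences. A response of this AGO1 regulator to pHBA is a hypothesis that stays open. With 1 library per dose, it and a difference between the RNA pools cannot be told apart.

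In PHBA 4 the log2 fold change was 3.22 for miR398, 0.44 for miR1444, -0.04 for miR408 and -1.42 for miR397. The difference of 4.64 between miR398 and miR397 sets apart the families already seen to lie furthest from each other. In these libraries the counting intervals of miR398 and miR397 lay on opposite sides of a ratio of 1. These families thus did not share 1 shift here. With 1 library per dose, whether the dose or a difference between the RNA pools parted them cannot be told.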
